A study of Mus musculus with 27 samples.

How the data were processed

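Retinas of 27 mice aged 9 months were measured by 3′ mRNA sequencing, with 100 ng of total RNA going into each library, per the labels' protocols. The labels place 7 libraries in the wildtype group, 7 in Gne+/-, 7 in C3-/- and 6 in Gne+/- C3-/-, and give each library a mouse number and a sequencing run, 1 or 2. The labels name a separate mouse for each library. The 3′ kit reads the end of each transcript, so a count does not depend on transcript length, and reads that fall outside a deleted exon can still be counted.

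The deposited values are raw counts per gene made by the authors, with no normalization. Reads were aligned with STAR 2.7.3a and counted with featureCounts, per the submitters' processing notes, which name Subread 2.0.0 and the builds GRCm38 and mm10. The version recorded with the counts was 2.0.3 and the annotation was Ensembl release 101, per the file headers. The series table held 55487 genes in 27 libraries and equalled the deposited counts of the single libraries. Reads were counted over both exon and whole-gene features, so reads in introns count too, with no strand setting and no option that assigns reads overlapping several genes, per the file headers. Reads that fall where annotated genes overlap, on either strand, are therefore left out of the counts of these genes. Of the protein-coding genes whose whole span is covered by other annotated genes, 1251 of 1251 were listed at 0 in all libraries, against 12.8% of the 11865 genes with no overlap. A listing of 0 for such a gene, such as B2m, P2ry12 or Cryaa, is therefore not a measure of its expression. Of 8858 protein-coding genes covered in part, 4.12% were at 0, among them Itgam, covered over 99.9% of its span. Xist, a non-coding gene, is covered over its whole span and is at 0 too. Symbols were matched to 55141 of the gene identifiers.

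Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group (minimum count 10), which left 17409 genes. Library sizes were scaled with TMM factors. Dispersions were estimated with estimateDisp, and the quasi-likelihood test was applied with robust estimation, with 22 residual degrees of freedom. The model held the 4 genotype groups and the sequencing run. The common biological coefficient of variation was 55.1%. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. CPM values use the TMM-scaled library sizes. No exact duplicate of a library was seen: over 78 pairs of the same group, the chi-square statistic per degree of freedom was at least 10.2.

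The groups, the model, the comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The comparisons were Gne+/- against wildtype, Gne+/- C3-/- against C3-/-, the difference of these 2 effects, C3-/- against wildtype, Gne+/- C3-/- against Gne+/-, and Gne+/- C3-/- against wildtype. Named genes were Gne and C3, up to 12 higher and 12 lower genes with the smallest p among those past the threshold (provisional gene symbols were counted and not named), up to 4 members with the smallest p of each list described, and a fixed set of complement, microglia, bipolar cell and glia genes in the Gne comparisons. Some genes that this rule takes are not reported here.

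Of 38 gene lists for retinal cell classes, complement, sialic acid metabolism, inflammation, stress and neighbouring tissues, 35 had at least 4 tested members and were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Beside it stand camera with a correlation estimated per list, and an exact 2-sided permutation test of the difference of run-centred mean list scores, with labels permuted within run. Adjusted p-values for lists cover the 35 lists.

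The procedure was tested on simulated counts with the real means, dispersions and library sizes, over 17409 genes with 100 changed by 2-fold and 100 by 4-fold. For Gne+/- against wildtype, 33% of the 2-fold and 60% of the 4-fold changes were recovered. The shares were 40% and 68% for Gne+/- C3-/- against C3-/-, 20% and 58% for the difference of the 2 Gne effects, 38% and 74% for C3-/- against wildtype, 44% and 64% for Gne+/- C3-/- against Gne+/-, and 44% and 65% for Gne+/- C3-/- against wildtype. Between 2 and 7 unchanged genes were also called in these simulations. With no change simulated, edgeR called 0 genes in each comparison. A shifted list was recovered in each comparison, with 0 other lists called. The simulated genes were drawn independently of each other. These values therefore do not test the error rates for genes or lists where genes vary together.

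Alternatives were DESeq2 1.42.0, RLE factors, no filter or a stricter filter on low counts (over 1 CPM in at least 6 libraries), limma-voom with quality weights, no robust estimation, no run term, each run alone, the mouse number as a block, scores of the lens and pigment epithelium lists as covariates, a score of sex-linked genes as a covariate (Xist is listed at 0 in all libraries, so the score follows the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d), a fit to the compared groups alone, and windows of 5 and 50 Mb around Gne and C3. For the correlations of effects, they were also genes above 3 log2 CPM, and all genes but those near Gne or C3. Added after seeing the data were the omission of each library, the omission of 3 libraries with few detected genes (wildtype mouse 7, C3-/- mouse 6 and Gne+/- mouse 4), lists in run 2 alone, the sialic acid synthesis list without Gne, and 2 forms of a leading component of variation as a covariate. The component of the residuals, from genes above 3 log2 CPM, was tried first, and the component of run-centred values was added after its result was known. An adjusted p that DESeq2 left undefined was kept undefined.

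Depth ranged from 13.5 to 34.2 M counts per library. Reads were not collapsed by molecular identifiers in the processing given, so PCR copies are not independent molecules. Splits of the samples were drawn within run, 100 per comparison with the real split included. Reads, exon-level counts and protein measurements were not analysed here.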

Results

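Retinas of 9-month-old mice were profiled by 3′ mRNA sequencing (QuantSeq) in a design that crosses heterozygous loss of Gne with loss of C3. Gne encodes the enzyme that starts sialic acid synthesis, and C3 is the central component of the complement cascade. The 27 libraries comprised 7 wildtype, 7 Gne+/-, 7 C3-/- and 6 Gne+/- C3-/- mice. Sequencing run 1 held 5, 5, 4 and 4 of these, and run 2 held 2, 2, 3 and 2. In wildtype mice 1, 2, 4, 5, 6, 7 and 8, the total counts were 19.5, 17.7, 18.6, 21.3, 18.5, 22.6 and 21 M. In Gne+/- mice 1, 2, 3, 4, 5, 7 and 8 they were 15.6, 13.5, 19.7, 19.1, 21.3, 27.8 and 24.9 M. In C3-/- mice 1, 2, 5, 6, 7, 8 and 9 they were 18.5, 13.7, 14.6, 14.8, 14.9, 34.2 and 15.3 M. In Gne+/- C3-/- mice 3, 4, 5, 6, 7 and 8 they were 18.1, 15.1, 17.4, 14.2, 15.2 and 22.8 M. The number of genes detected ranged from 16459 to 22938. PCR reads without molecular identifiers are not independent molecules, and the errors of log2 fold changes include the spread between mice.

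The runs differed strongly. Between run 2 and run 1, 10354 of 17409 tested genes (59.5%) passed the edgeR threshold, 5272 higher and 5082 lower. A single ribosomal RNA-like gene took 1.46% to 4.58% of the counts in run 2 and 0.00121% to 0.0112% in run 1. The mean of 4 Y-linked genes (Ddx3y, Uty, Eif2s3y and Kdm5d) was above a minimum of 10 CPM in 0 of 5 wildtype and 4 of 4 C3-/- libraries of run 1, and in 2 of 2 wildtype and 0 of 3 C3-/- libraries of run 2. It was above this minimum in 2 of 5 Gne+/- and 2 of 4 Gne+/- C3-/- libraries of run 1, and in 2 of 2 of each in run 2.

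The targeted genes followed the genotype labels in all libraries. Gne (ENSMUSG00000028479, chromosome 4, 44034075 to 44084177, GRCm38) measured 161.6, 99.2, 132.3, 121.8, 131.5, 47.01 and 55.46 CPM in wildtype mice 1, 2, 4, 5, 6, 7 and 8, and 49.5, 56.74, 49.58, 48.23, 33.87, 16.39 and 13.05 CPM in Gne+/- mice 1, 2, 3, 4, 5, 7 and 8. It measured 109.6, 110.5, 135.6, 110.9, 43.02, 45.02 and 45.83 CPM in C3-/- mice 1, 2, 5, 6, 7, 8 and 9, and 42.06, 40.08, 32.04, 44.04, 13.01 and 14.12 CPM in Gne+/- C3-/- mice 3 to 8. In run 1 the means were 129 ± 22.5 CPM in wildtype (SD, n = 5), 47.6 ± 8.37 in Gne+/- (n = 5), 117 ± 12.6 in C3-/- (n = 4) and 39.6 ± 5.26 in Gne+/- C3-/- (n = 4). In run 2 they were 51.2 ± 5.97 (n = 2), 14.7 ± 2.37 (n = 2), 44.6 ± 1.45 (n = 3) and 13.6 ± 0.786 (n = 2). Within each run, every Gne-heterozygous library lay below every library with both copies. Where 3′ reads fall outside the deleted part of a gene, a lack of change would check nothing, and the position of the deleted parts was not used here.

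C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136) measured 188.1, 100.5, 132.3, 173, 216.2, 53.85 and 91.37 CPM in wildtype mice 1, 2, 4, 5, 6, 7 and 8, and 128.5, 124.6, 118.5, 100.9, 285.1, 95.58 and 75.89 CPM in Gne+/- mice 1, 2, 3, 4, 5, 7 and 8. It measured 0.662, 0, 1.143, 1.275, 0.4917, 0.4405 and 3.598 CPM in C3-/- mice 1, 2, 5, 6, 7, 8 and 9, and 0.5455, 0.9674, 1.689, 1.835, 0.4139 and 0 CPM in Gne+/- C3-/- mice 3 to 8. Run 1 means were 162, 152, 0.770 and 1.26 CPM in wildtype, Gne+/-, C3-/- and Gne+/- C3-/- mice, and run 2 means were 72.6, 85.7, 1.51 and 0.207 CPM.

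**Figure D1:**
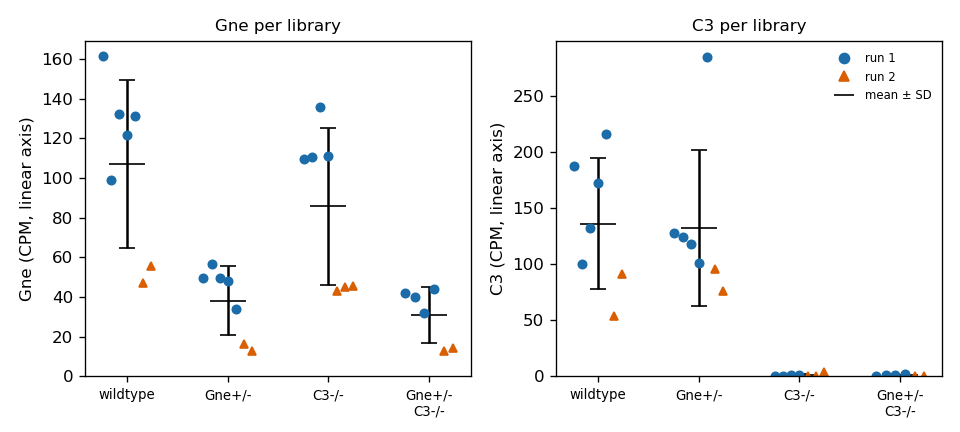
Gne (left) and C3 (right) in CPM on linear axes for each library by genotype, with run 1 as circles, run 2 as triangles, and the mean ± SD of each group as bars. C3 lies at or below 3.598 CPM in all libraries without C3, and Gne is lower in run 2 than in run 1 in each genotype.

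The comparison of Gne+/- with wildtype mice addresses the effect on the retina of losing a copy of Gne, meant to lower sialylation, which was not measured here. Gne fell by 1.54 on the log2 scale (SE 0.13, adjusted p = 3.32e-09, edgeR, n = 7 and 7), to 34.3% of its wildtype level, and was the only gene past the threshold among 17409. The sialic acid synthesis list, which holds the targeted gene itself, passed as lower (6 of 6 tested members negative, median log2 fold change -0.26, mean -0.51; camera adjusted p = 0.000199; adjusted p = 0.00924 with an estimated correlation). Without Gne, an alternative chosen after seeing the data, it did not pass (5 of 5 negative, median -0.20, camera adjusted p = 0.229; adjusted p = 0.461 with an estimated correlation). With Gne in it, the exact permutation test of the list score gave p = 0.0132 (adjusted p = 0.347). Of its members, 1 passed over all genes and 1 adjusted over the list alone, Gne in both cases. Cmas, which activates sialic acid, stood at -0.19 (SE 0.148), Cmah at -0.32 (SE 0.255) and Renbp at -0.59 (SE 0.502). The difference of the list score, Gne included, was -0.477 in run 1 and -0.543 in run 2.

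Genes of the lens, an eye tissue next to the retina, rose as a list (11 of 11 members positive, median 3.39, mean 3.58; camera adjusted p = 8.22e-08; adjusted p = 0.37 with an estimated correlation). Over all genes 0 members passed in the main edgeR fit and by limma-voom, 1 (Crybb1) by DESeq2 and 6 in edgeR without the low-count filter, and 7 passed in the main fit adjusted over the list alone. The lens crystallin Crybb1 stood at 4.21 (SE 1.14), from 0.312 ± 0.251 to 5.31 ± 7.12 CPM, and Crygc measured 0 CPM in wildtype and 0.838 ± 1.46 CPM in Gne+/- mice. The lens gap junction gene Gja3 stood at 4.44 (SE 1.44) and Mip, the main water channel of lens fibres, at 2.35 (SE 0.845). The mean list score was 4 log2 units higher in Gne+/- mice in run 1 (SE 0.926, 5 against 5 libraries) and differed by -0.674 in run 2 (SE 0.621, 2 against 2 libraries). A permutation of the list score within run gave p = 0.0198 (exact, 2-sided; adjusted p = 0.347).

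Markers of bipolar cells and microglia, which the study's title names, did not pass. Of 18 tested genes of cone and OFF bipolar cells, 14 were negative (median -0.14, camera adjusted p = 0.125; adjusted p = 0.395 with an estimated correlation), with Grik1, a kainate receptor of OFF bipolar cells, at -0.29 (SE 0.131) and Scgn at -0.27 (SE 0.128). The list score differed by -0.0954 in run 1 and -0.0771 in run 2. For ON and rod bipolar cells the median was -0.03 (adjusted p = 0.806), with Prkca, a rod bipolar kinase, at -0.02 (SE 0.122) and Trpm1, the ON bipolar cation channel, at -0.27 (SE 0.144). The activated microglia and lysosome list had 14 of 21 members positive (median 0.25, adjusted p = 0.527) and the homeostatic microglia list 7 of 10 (median 0.37, adjusted p = 0.659). Aif1 stood at 0.38 (SE 1.11), Tmem119 at -0.24 (SE 0.663) and Cd68 at 0.63 (SE 1.01), each below 2 CPM in wildtype, with errors that leave changes in either direction open.

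Complement genes did not pass in this comparison either, C3 included (-0.01, SE 0.455, edgeR adjusted p = 0.997). C1qa stood at 0.50 (SE 0.353), C1qb at -0.09 (SE 0.73) and C1qc at -0.29 (SE 0.402), the genes of the initiating C1q complex. C4b stood at -0.88 (SE 0.601) and the receptor C3ar1 at 0.41 (SE 0.699). Complement components (6 of 12 positive) had an adjusted p of 0.859, and receptors and regulators (5 of 10 positive) 0.659. Itgam, a complement receptor subunit, is listed at 0 in all libraries, with 99.9% of its span overlapped by other genes, and was not measurable. Gfap, an intermediate filament of reactive glia, stood at 0.88 (SE 0.39), and the gliosis list had 10 of 12 members positive (adjusted p = 0.211; 0 members over all genes and 1 adjusted over the list alone). Retinal astrocyte genes moved the same way (5 of 6 positive, adjusted p = 0.301). The 33 lists that did not pass had adjusted p-values from 0.125 to 0.975, among them pigment epithelium and melanocyte at 0.691. The fibroblast and sclera score, of another neighbouring tissue, differed by 0.66 (exact permutation p = 0.0635, adjusted p = 0.364). It differed by 0.756 in run 1 and 0.42 in run 2, while the erythrocyte score differed by -0.292 over both runs. The median, the mean and the test differed in sign for rod and cone photoreceptors, Mueller glia, sialyltransferases, sialidases, interferon response, cytokine and NF-kB signalling, photoreceptor and ribbon synapse, nuclear oxidative phosphorylation and ribosomal proteins, none of which passed.

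At an unadjusted p under 0.05 there were 1003 genes, where 870 are the number chance gives. DESeq2 called 8 genes and limma-voom 1. Without the run term edgeR called 0 genes, and Gne, at -1.49, had an adjusted p of 1.

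**Figure D2:**
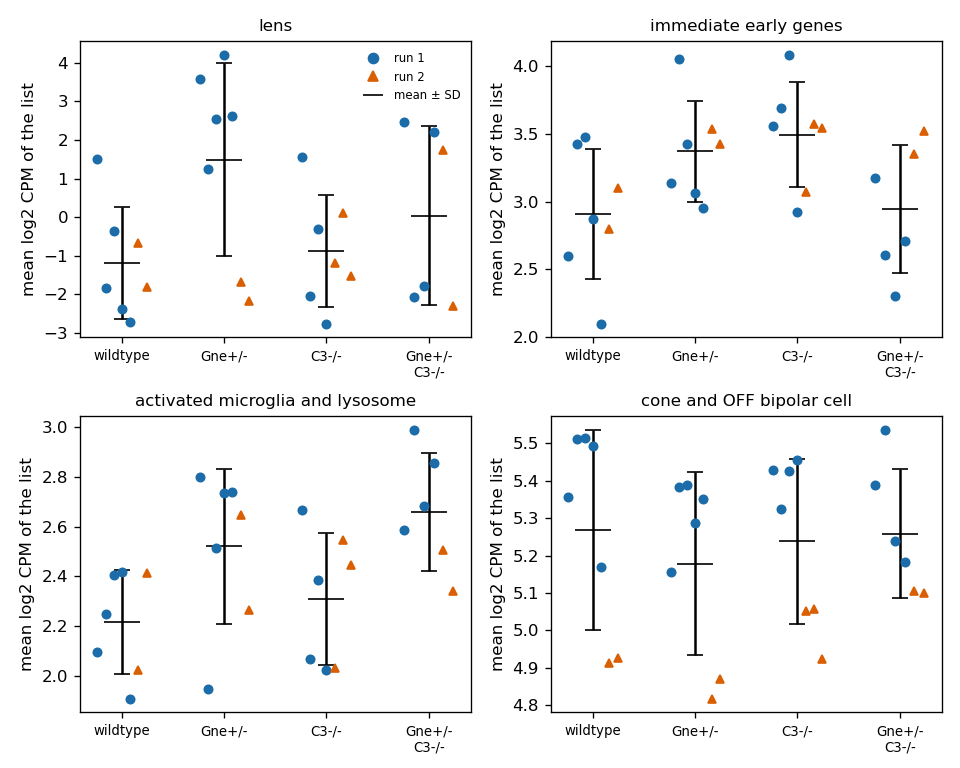
Mean log2 CPM per library of the lens, immediate early, activated microglia and lysosome, and cone and OFF bipolar cell lists, by genotype, with run 1 as circles, run 2 as triangles, and the mean ± SD of each group as bars. The lens score of Gne+/- libraries has a mean of 2.84 in run 1 and -1.92 in run 2.

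The comparison of Gne+/- C3-/- with C3-/- mice asks what Gne loss does without C3. Gne fell by 1.62 (SE 0.138, adjusted p = 4.46e-09, edgeR, n = 6 and 7), to 32.5% of its level in C3-/- mice, and was again the only gene past the threshold. The sialic acid synthesis list passed with Gne in it (3 of 6 members negative, median -0.10, mean -0.30; camera adjusted p = 0.0201; adjusted p = 0.0742 with an estimated correlation), with 1 member past the threshold over all genes and 1 adjusted over the list alone, both Gne. Without Gne it did not pass (2 of 5 negative, median 0.01, mean -0.04; camera adjusted p = 0.983). Immediate early genes, which respond within minutes to activity or stress, fell as a list (11 of 11 negative, median -0.39; adjusted p = 0.00136; adjusted p = 0.219 with an estimated correlation). The activated microglia and lysosome list rose (17 of 21 positive, median 0.26; adjusted p = 0.0201; adjusted p = 0.0742 with an estimated correlation).

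In neither of the last lists did a member pass, over all genes (0, as by DESeq2, by limma-voom and without the low-count filter) or adjusted over the list alone (0). Among immediate early genes Nr4a1 stood at -0.44 (SE 0.256), Fos at -0.68 (SE 0.437), Junb at -1.17 (SE 0.787) and Dusp1 at -0.39 (SE 0.278). Their list score differed by -0.866 in run 1 and 0.0424 in run 2, and the permutation test gave p = 0.0586 (exact, 2-sided). Against wildtype, this score was higher in C3-/- mice (0.58, exact permutation p = 0.0278, adjusted p = 0.486). It was higher in Gne+/- mice too (0.462, exact permutation p = 0.0728, adjusted p = 0.364). In the microglia list, the receptor Axl stood at 0.60 (SE 0.354), the microglial receptor Trem2 at 1.52 (SE 1.08), Lpl at 0.26 (SE 0.195) and Lgals3 at 0.64 (SE 0.603). Its score differed by 0.49 in run 1 and 0.081 in run 2, with p = 0.0457 by the exact permutation test (adjusted p = 0.442). The smallest exact permutation p here was that of the Mueller glia list, which did not pass (p = 0.0329, adjusted p = 0.442). The Mueller glia score differed by -0.0819, with -0.0826 in run 1 and -0.0829 in run 2. Beside these lists, the lens list had a median of 1.28 (adjusted p = 0.0659) and the pigment epithelium and melanocyte list 0.46 (adjusted p = 0.0659), both tissues next to the retina.

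The fixed genes given here did not pass in this comparison, each with an adjusted p of 1. C1qa stood at 0.17 (SE 0.367), C1qb at -0.74, C1qc at 0.33, C4b at 0.05, C3ar1 at -0.30, Aif1 at 0.39, Tmem119 at -0.19 and Cd68 at 0.28. Prkca stood at -0.03 (SE 0.127), Trpm1 at -0.03 (SE 0.15) and Gfap at -0.19 (SE 0.411). For cone and OFF bipolar cells the test pointed down with a median of 0.01 (adjusted p = 0.961). Signs also differed for rod photoreceptors, Mueller glia, sialyltransferases, antigen presentation, photoreceptor and ribbon synapse, pericyte and smooth muscle, and retinal astrocytes, none of which passed. The 32 lists that did not pass had adjusted p-values from 0.0659 to 0.983. At an unadjusted p under 0.05 there were 235 genes, against 870 by chance. DESeq2 and limma-voom each called 1 gene, and edgeR without the run term called 0.

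Whether the Gne effect differs with and without C3 was tested as an interaction. Gne itself differed by -0.08 (SE 0.184) between the effects, and edgeR called 0 genes (554 at an unadjusted p under 0.05), as did DESeq2 and limma-voom (0 each). Immediate early genes had a lower Gne effect without C3 (11 of 11 negative, median -0.63; adjusted p = 0.00108; adjusted p = 0.611 with an estimated correlation), with Junb at -2.84 (SE 1.08) and Jun at -0.72 (SE 0.429). The lens list also had a lower effect (10 of 11 negative, median -2.35; adjusted p = 0.025; adjusted p = 0.732 with an estimated correlation), with Gja3 at -3.63 (SE 1.99). In the main fit no member of either list passed, over all genes (0) or adjusted over the list alone (0). Without the low-count filter Junb, Egr1, Cryba2, Cryba4, Crybb2 and Crygs did over all genes, the last 5 named after their values were seen. The other 33 lists had adjusted p-values from 0.161 to 0.937. Among these, the median, the mean and the test differed in sign for rod photoreceptors, amacrine cells, Mueller glia, homeostatic and activated microglia, complement receptors and regulators, sialidases, nuclear oxidative phosphorylation, ribosomal proteins, circadian clock, endothelium, and fibroblast and sclera. Across 17409 genes, which are not independent replicates, the correlation of the Gne effects was r = 0.0129 (permutation p = 0.32) and rho = -0.00458 (permutation p = 0.47). These effects share no library.

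The comparison of C3-/- with wildtype mice sets the C3 genotypes against each other with Gne intact. An effect of C3 loss cannot be told apart here from sequence of another strain that C3-/- mice may carry. Besides C3, which fell by 6.72 (SE 0.618, adjusted p = 6.08e-07), 28 genes passed the edgeR threshold, so that 13 rose and 16 fell in all (n = 7 and 7). Heatr5a rose by 1.27 (SE 0.124, adjusted p = 5.42e-08; ENSMUSG00000035181, chromosome 12, 51875871 to 51971321), from 47.2 ± 7.92 to 122 ± 32.6 CPM. Rab6a, a GTPase of Golgi transport, rose by 0.91 (SE 0.147, adjusted p = 0.000922; ENSMUSG00000030704, chromosome 7, 100607410 to 100641268), from 182 to 339 CPM. Slc4a8, a sodium-driven bicarbonate exchanger, fell by 1.22 (SE 0.168, adjusted p = 5.47e-05; ENSMUSG00000023032, chromosome 15, 100761747 to 100823968), from 89.6 to 37.7 CPM.

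Further genes that rose were Ints4 (1.11), a subunit of the Integrator complex, Arhgap31 (0.98), Pgap2 (0.76), Myg1 (1.02), the telomere protein gene Pot1b (2.51, 3.29 to 16.7 CPM; ENSMUSG00000024174, chromosome 17, 55651951 to 55712628) and the ribosomal protein gene Rps15a (3.96, 20.3 to 242 CPM; ENSMUSG00000008683, chromosome 7, 118104372 to 118116188). Others that fell were Akap6 (-0.71), Xxylt1 (-1.47), Mylk (-0.63), the transcription factor gene Sp1 (-1.01) and the cholesterol transporter gene Abca1 (-0.86). Trim12a measured 0.00732 CPM in wildtype and 5.09 CPM in C3-/- mice, Olfr607 3.20 and 0 CPM, Mrpl48-ps 3.91 and 0.0181 CPM, and Tmem181b-ps 46.3 and 0.0995 CPM. The pseudogenes Rps13-ps1 (chromosome 8, 87047689 to 87048226), at 245 against 3.61 CPM, and Rps13-ps2, at 0.039 against 7.70 CPM, are uncertain, since they resemble Rps13. Rps13 itself measured 27.8 ± 41 and 254 ± 65.3 CPM, and the sum of the 3 was 273 ± 66 in wildtype and 265 ± 75 CPM in C3-/- mice. The counts thus shifted between the copies with C3 genotype, while their sum differed by less than its SD. Of the 29 genes, 4 were pseudogenes and 6 had provisional symbols. Rab6a, Ints4, Arhgap31, Pgap2, Myg1, Pot1b, Akap6, Xxylt1, Mylk, Trim12a and C3 overlap other annotated genes, as do Cers5, Aldh7a1 and Knstrn named further on. Reads in the overlap are missing from their counts.

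The called genes were unevenly placed. Chromosome 7 held 11 of 29, between 84.53 and 140 Mb, with 7.47% of the tested genes. Chromosome 17 held 5, and chromosomes 15 and 16 held 4 each, those on 15 between 100.8 and 102.4 Mb. Within 20 Mb of C3 lay 3 of the other 28 called genes, against 1.48% of tested genes (odds ratio 8.06, one-sided Fisher exact p = 0.00802). By the same test p was 0.000215 within 5 Mb (odds ratio 29.6) and 0.132 within 50 Mb. The test takes genes as independent, while some of these 3 genes lie side by side. Sex, as read from the Y-linked genes at this minimum of 10 CPM, differed between the genotypes within each run, in opposite directions. None of the 35 lists passed (0; lowest adjusted p 0.27, highest 0.992; 0 with an estimated correlation). Signs of median, mean and test differed for cone and OFF bipolar cells, ganglion cells, gliosis, activated microglia, complement receptors, sialic acid receptors, antioxidant response, antigen presentation, cytokines, mitochondrial oxidative phosphorylation, circadian clock, endothelium, astrocytes, pigment epithelium, and fibroblast and sclera. DESeq2 called 63 genes, limma-voom 72, and edgeR without the run term 13.

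**Figure D3:**
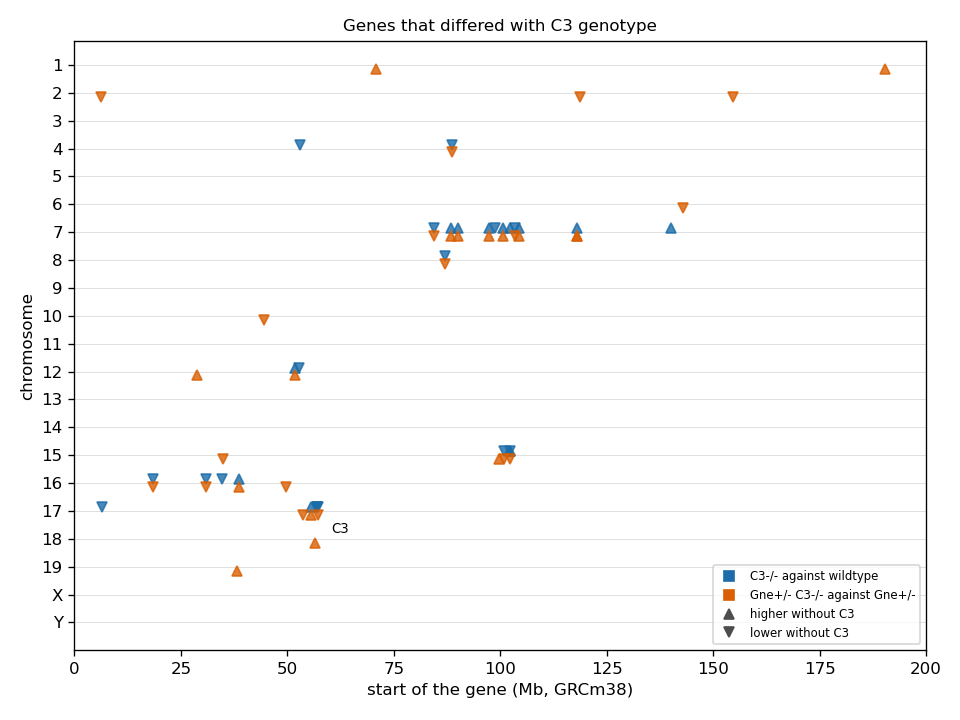
Position on GRCm38 of the genes that passed the threshold in C3-/- against wildtype (blue) and in Gne+/- C3-/- against Gne+/- (orange), by chromosome and start in Mb, with triangles up for genes higher and down for genes lower without C3. Chromosome 7 holds 11 of the 29 and 9 of the 33 genes.

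With Gne heterozygous, the genes that differed with C3 genotype overlapped the former. In Gne+/- C3-/- against Gne+/- mice 33 genes passed, 16 higher and 17 lower (edgeR, n = 6 and 7). The balance was not kept without the low-count filter (71 higher and 235 lower) or with a residual component as a covariate, an alternative chosen after seeing the data (90 higher and 306 lower). Of the 33 genes, 18 were also called in C3-/- against wildtype, 9 higher and 9 lower, where independent lists would share 0.055. C3 fell by 7.26 (SE 0.673, adjusted p = 7.02e-07), Heatr5a rose by 1.18 (SE 0.127), Rab6a by 0.93 (SE 0.151), Arhgap31 by 1.17, Pot1b by 3.02 and Rps15a by 3.93, and Slc4a8 fell by 1.11 (SE 0.175), Xxylt1 by 1.52 and Sp1 by 0.95. Trim12a measured 0 and 4.51 CPM in Gne+/- and Gne+/- C3-/- mice, Olfr607 2.46 and 0 CPM and Mrpl48-ps 5.78 and 0.0065 CPM. Rps13-ps1 measured 233 and 3.34 CPM, and Rps13-ps2 0.00732 and 9.53 CPM.

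Genes past the threshold here and not in C3-/- against wildtype included Pde6c, the cone phosphodiesterase, which rose by 0.72 (SE 0.15, adjusted p = 0.0245; ENSMUSG00000024992, chromosome 19, 38132781 to 38183958), and Cd47, a surface protein that limits phagocytosis, which fell by 0.70 (SE 0.152, adjusted p = 0.0358; ENSMUSG00000055447, chromosome 16, 49800533 to 49915010), from 302 ± 89.2 to 177 ± 22.9 CPM. The ceramide synthase gene Cers5 rose by 0.89, Arl6ip1 by 0.72, Aldh7a1 by 0.66 and Trappc12 by 0.79. Stk3 fell by 0.84, Knstrn by 0.88 and Prdm1, a transcription factor of retinal cell fate, by 0.76. The edgeR interaction test called 0 genes (554 at an unadjusted p under 0.05, 0 by DESeq2 and by limma-voom), so no gene was shown to differ between the C3 effects.

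Among the lists, mitochondrially encoded oxidative phosphorylation rose (7 of 8 positive, adjusted p = 0.0439; adjusted p = 0.371 with an estimated correlation), with mt-Nd4, a subunit of complex I, at 0.43 (SE 0.177). Gliosis genes fell (8 of 12 negative, adjusted p = 0.0439; adjusted p = 0.371 with an estimated correlation), with Cd44 at -0.74 (SE 0.24), Serpina3n at -2.43 (SE 0.848) and Gfap at -0.78 (SE 0.407). The retinal astrocyte list, which did not pass (5 of 6 negative, adjusted p = 0.237), moved the same way, with a score difference of -0.596 (exact permutation p = 0.0635; -0.76 in run 1 and -0.234 in run 2), against -0.488 for gliosis (p = 0.0833). The Mueller glia list did not pass either. Its score differed by -0.122 (exact permutation p = 0.0225, adjusted p = 0.208), with -0.138 in run 1 and -0.087 in run 2. The gliosis score of Gne+/- C3-/- mouse 8 was 1.08, with the next library of its group at 2.33, and without this mouse the gliosis list did not pass (adjusted p = 0.222). The gliosis list passed in 2 of 12 alternative settings and without 15 of 27 single libraries, the mitochondrial list in 3 of 12 and without 13 of 27, and the lens list in 3 of 12 and without 17 of 27. Lens genes fell (9 of 11 negative, adjusted p = 0.0439; adjusted p = 0.479 with an estimated correlation), with Mip at -2.36 (SE 0.907). No member of these lists passed in the main fit, over all genes (0, as by DESeq2 and limma-voom) or adjusted over the list alone (0). Without the low-count filter 5 lens members (Mip, Cryba2, Cryba4, Crybb2 and Crygs), 2 mitochondrial members (mt-Nd3 and mt-Nd4) and 1 gliosis member (Serpina3n) did over all genes, Cryba2, Cryba4, Crybb2, Crygs and mt-Nd3 being named after their values were seen. The mitochondrial score differed by 0.324 in run 1 and 0.301 in run 2, the gliosis score by -0.364 and -0.768, and the lens score by -2.64 and 1.63. The 32 lists that did not pass had adjusted p-values from 0.0684 to 0.974, including cone photoreceptors, with 1 member (Pde6c) past the threshold over all genes and 2 adjusted over the list alone. Antigen presentation, also among these, had the smallest exact permutation p of the lists in this comparison (p = 0.00265, adjusted p = 0.0928). Its score differed by -0.541, with -0.449 in run 1 and -0.75 in run 2. The median, the mean and the test differed in sign for rod photoreceptors, complement components, complement receptors, sialyltransferases, cytokines, nuclear oxidative phosphorylation and circadian clock, none of which passed.

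DESeq2 called 87 genes, limma-voom 59, and edgeR 13 without the run term and 20 with the compared groups alone. Without Gne+/- C3-/- mouse 3, edgeR called 20. At an unadjusted p under 0.05 there were 1114 genes here and 781 in C3-/- against wildtype. Across genes, the C3 effects, which share no library, correlated with r = 0.195 (permutation p = 0.01, the smallest that 100 splits can give), rho = 0.157 (permutation p = 0.12) and a covariance of 0.0963. Among the 9963 genes above 3 log2 CPM, r was 0.501 (permutation p = 0.05).

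The comparison of Gne+/- C3-/- with wildtype mice combines both genotypes. Gne fell by 1.77 (SE 0.139) and C3 by 7.28 (SE 0.673), and 27 genes passed in all, 13 higher and 14 lower (edgeR, n = 6 and 7). Rec8, a meiotic cohesin gene, measured 0.377 CPM in wildtype and 8.09 CPM in Gne+/- C3-/- mice (log2 fold change 4.99, SE 1.06, adjusted p = 0.04). Pde6c rose by 0.70 (SE 0.151) and Cd47 fell by 0.69 (SE 0.152). The sialic acid synthesis list passed with Gne in it (5 of 6 negative; adjusted p = 0.0237; adjusted p = 0.0992 with an estimated correlation), with 1 member, Gne, over all genes and adjusted over the list alone (1), and did not pass without Gne (4 of 5 negative, adjusted p = 0.653). The other 34 lists had adjusted p-values from 0.0575 to 0.987, and the signs of median, mean and test differed for ON and rod bipolar cells, cone and OFF bipolar cells, amacrine cells, complement components, sialyltransferases, antioxidant response, immediate early genes and astrocytes. At an unadjusted p under 0.05 there were 863 genes. DESeq2 called 56 genes, limma-voom 47, and edgeR without the run term 13.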

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

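The tests of the placement of called genes away from C3, of sex, of lens genes other than crystallins, of the lens score within each run, and both tests of the Gne level were chosen only after the results were seen. Samples far from the rest of their group were sought in 40 sets of 6 or 7 values, where chance gives about 1 in 20, or 2, and 5 were found. C3-/- mouse 8 had 34.2 M counts, with the next library of its group at 18.5. Gne+/- mouse 5 had 285.1 CPM of C3, with the next at 128.5. C3-/- mouse 9 had 3.598 CPM of C3, with the next at 1.275. The sialic acid synthesis score of Gne+/- mouse 8 was 3.43, with the next at 4.04, and the gliosis score of Gne+/- C3-/- mouse 8 was 1.08, with the next at 2.33. The effects of Gne with and without C3 differed for immediate early genes (adjusted p = 0.00108; adjusted p = 0.611 with an estimated correlation) and for the lens list (adjusted p = 0.025; adjusted p = 0.732 with an estimated correlation) by a test of the difference itself with a preset correlation, and neither held with an estimated one.

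The 29 genes called in C3-/- against wildtype are clustered along chromosomes. A sex difference as the whole source is argued against, since 26 of 29 genes remained called with the sex-linked score as a term, although sex and genotype are confounded within each run. Sex by the Y-linked genes was reversed between the runs. In 23 of the 29 genes, the targeted C3 among them, the genotypes did not overlap within either run, in the same direction. This argues against sex as the whole source for these 23. It is not an independent test, as the genes were called for a difference over both runs, which favours such a pattern. Flanking sequence of a donor strain around the C3 allele is a candidate explanation for the 3 called genes within 20 Mb (Fisher exact p = 0.00802; in Gne+/- C3-/- against Gne+/- 2 of 32, p = 0.0812), among them Slc25a41, named here after its value was seen. Slc25a41 ends at 57041654 and another of the 3 starts at 57041775, so they may not be independent and the Fisher p may be too small. Segments of another strain elsewhere may account for others: of 25 called genes away from C3, 18 lie within 5 Mb of another, where random draws gave a median of 2 and at most 14 (permutation p = 1e-04, the smallest that 10000 draws can give), and in Gne+/- C3-/- against Gne+/- 12 of 30 did (permutation p = 0.006). An effect of C3 loss on these genes stays open, and near Gne the called genes other than Gne numbered 0, which left no test of its flanks.

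The lens list passed as higher in Gne+/- than in wildtype mice with a preset correlation (adjusted p = 0.37 with an estimated correlation, 0.347 by the exact permutation test). The rise of the score by 4 (SE 0.926) in run 1 was not repeated in run 2, where it differed by -0.674 (SE 0.621, 2 against 2 libraries). With so few libraries and a difference close to its SE, run 2 cannot tell whether a genotype difference is present in both runs. Chance could not be excluded, as 18 of 100 splits within run also called this list. A genotype effect stays open, and so does lens tissue carried into some samples: lens genes other than crystallins (Mip, Bfsp1 and Gja3) had a median log2 fold change of 3.11, but all 11 members of the list were known to be positive, so this value decides nothing.

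Gne fell below the level that a single intact copy would leave if transcripts followed copy number. Chance around that level is argued against, as the higher upper end of both 95% intervals of the log2 fold change was -1.29. The scaling of the libraries is argued against too, since over DESeq2, RLE factors, limma-voom and no run term the highest log2 fold change was -1.47. The position of the 3′ reads relative to the targeted part of Gne was not tested, and a biological lowering of the intact copy may also account for it, as a hypothesis.

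Splits of the same libraries within run, 100 per comparison with the real one included, bear on chance. For Gne+/- against wildtype, 5 splits called at least as many genes as the real 1, so chance could not be excluded for the count, and the highest other called 863, which points to a structure of the samples: it puts wildtype mice 1, 5, 6 and 8 with Gne+/- mice 4, 5 and 7. For Gne+/- C3-/- against C3-/- only the real split (1 of 100) gave its 1 gene and the highest other gave 0, so chance was excluded for that gene, which is Gne itself, and this says nothing about other effects of Gne loss. For the difference of the Gne effects, all 100 splits gave at least the real 0, as they must. Chance was excluded for C3-/- against wildtype (real 29, highest other 0), Gne+/- C3-/- against Gne+/- (33 and 0) and Gne+/- C3-/- against wildtype (27 and 10), each reached by 1 split, the real one.

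For the numbers of lists chance could not be excluded. As many lists as the real number were called in 7 splits for Gne+/- against wildtype (real 2, highest other 3), 14 for Gne+/- C3-/- against C3-/- (3 and 5), 20 for the difference (2 and 4) and 7 for Gne+/- C3-/- against Gne+/- (3 and 4). For C3-/- against wildtype the real number is 0 (highest other 4), which all 100 splits reach by construction, so it tests nothing. The immediate early genes were called for the difference in 12 splits, so chance could not be excluded. The activated microglia and lysosome list was called for Gne+/- C3-/- against C3-/- in 3 splits, the real one included, which excludes chance for this list only if it is taken alone. Over the 35 lists it did not pass the exact permutation test (p = 0.0457, adjusted p = 0.442) or the test with an estimated correlation (adjusted p = 0.0742). The correlation of the Gne effects was reached in 32 splits (real 0.0129, highest other 0.161) and chance could not be excluded, while that of the C3 effects was reached by 1, the real one (0.195 and 0.178), so chance was excluded for r over all genes. This r takes in genes with large changes in both C3 comparisons, such as Trim12a (8.553 and 9.405) and Rps13-ps1 (-6.103 and -6.248). How far it rests on them was not tested. Without genes near Gne or C3, which leaves out C3 itself, r was 0.186. For rho (0.157) 12 splits were as high, and for r among genes above 3 log2 CPM (0.501) 5 were, so for these chance could not be excluded.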

How the results depend on the processing

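The omission of single libraries, the omission of 3 libraries with few detected genes, lists in run 2 alone, the sialic acid synthesis list without Gne and both component covariates were chosen after seeing the data. Of 562 values for the main results, 466 kept their direction and side of the threshold, or stayed within 1.5 times for counts, 93 moved and 3 fell below the threshold. Of 14889 values for single genes and lists, 14011 stayed, 493 moved, 86 gained and 292 lost the threshold, and 7 changed sign. Except where the construction shows it, the cause was not tested.

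Counts of genes are given in the order Gne+/- against wildtype, Gne+/- C3-/- against C3-/-, the difference, C3-/- against wildtype, Gne+/- C3-/- against Gne+/-, and Gne+/- C3-/- against wildtype, where the values were 1, 1, 0, 29, 33 and 27. Without the low-count filter they were 72, 9, 30, 91, 306 and 118. In the first, the added genes with the smallest p include the Y-linked Eif2s3y, Uty, Ddx3y and Kdm5d. They also include the crystallins Crybb2, Cryba2, Crygs, Cryab and Cryba4, beside Acp1 and Prrc2a, all named after their values were seen. The Y-linked genes were above 10 CPM in 0 of 5 wildtype and 2 of 5 Gne+/- libraries of run 1. DESeq2 gave 8 in the first and 63, 87 and 56 in the last 3, and limma-voom 72, 59 and 47 in the last 3. Without the run term they were 0 and 0 in the first pair and 13, 13 and 13 in the last 3, and Gne, at -1.49, had an adjusted p of 1, as the difference between runs then counts as spread. In run 2 alone, with fewer samples, they were 5 in Gne+/- C3-/- against C3-/-, 4 in the difference (the 4 added genes, the same in both, include the Y-linked Ddx3y, Eif2s3y and Kdm5d, and the Y-linked genes were above 10 CPM in 0 of 3 C3-/- and 2 of 2 Gne+/- C3-/- libraries of this run), 11 in Gne+/- C3-/- against Gne+/- and 15 in the last, and C3, at -5.68, had an adjusted p of 0.556. With only the compared groups, Gne+/- C3-/- against Gne+/- gave 20. With the component of the residuals as a covariate, tried first, they were 65 in the first, 7 in the difference, and 52, 396 and 57 in the last 3. A residual component cannot remove a group shift along its own axis, and of 64 added genes in the first, 60 have a loading, 50 of them among the highest. With the run-centred component they were 45 in C3-/- against wildtype and 45 in the last. Of the 29 genes of C3-/- against wildtype, 29 were shared with DESeq2, 27 with limma-voom and 13 with no run term.

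Lists called numbered 2, 3, 2, 0 and 3 in the first 5 comparisons. With an estimated correlation they were 1 in Gne+/- against wildtype and 0 in Gne+/- C3-/- against C3-/-, in the difference and in Gne+/- C3-/- against Gne+/-. The permutation test gave 0 in Gne+/- against wildtype, in Gne+/- C3-/- against C3-/- and in Gne+/- C3-/- against Gne+/-. With the sialic acid synthesis list taken without Gne, 1 was called in Gne+/- against wildtype, and that list turned direction in Gne+/- C3-/- against C3-/- (adjusted p = 0.983). In run 2 alone they were 4, 0 and 0 in the first 3. With lens and pigment epithelium scores as covariates they were 1, in the difference 1, and in Gne+/- C3-/- against Gne+/- 0. Without the run term they were 5 in Gne+/- C3-/- against C3-/- and 1 in Gne+/- C3-/- against Gne+/-, where run 1 alone gave 1, the sex covariate 0, and the omission of 3 libraries with few detected genes 1. The residual component gave 1 in the difference and 0 in Gne+/- C3-/- against Gne+/-, and the run-centred component 4, 1 in the difference, 1 in C3-/- against wildtype and 0 in Gne+/- C3-/- against Gne+/-. The lens list turned direction in run 2 alone (adjusted p = 0.706 in Gne+/- against wildtype, 0.648 in the difference, 0.263 in Gne+/- C3-/- against Gne+/-) and with lens and pigment epithelium scores as covariates (0.897 and 0.991 in the first and the difference), which remove it by construction. Immediate early genes turned in Gne+/- C3-/- against C3-/- in run 2 alone (adjusted p = 0.812). The correlation of the C3 effects was 0.501 above 3 log2 CPM and 0.139 with the lens and pigment epithelium scores. The 3 genes near C3 had a one-sided Fisher exact p of 0.132 in a window of 50 Mb and 0.000215 in a window of 5 Mb.

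The mouse numbers do not pair the samples: of 31 pairs with the same number, 11 correlated above 0.1 (lowest -0.24, median -0.037), and 8 of 27 libraries correlated best with their own number. With the replicate block, the gene counts were 1, 1, 0, 23, 27 and 24, and lists numbered 4 in Gne+/- against wildtype and 1 in the difference.

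Leaving out each library in turn, gene counts ranged from 1 to 2 (2 without Gne+/- mouse 5), 1 to 1, 0 to 0, 25 to 35, 20 to 40 (20 without Gne+/- C3-/- mouse 3) and 19 to 29. Gne ranged from -1.60 to -1.48 and C3 from -7.57 to -6.45. Lists ranged from 2 to 4 in Gne+/- against wildtype (4 without wildtype mouse 6) and 0 to 1 in C3-/- against wildtype (1 without wildtype mouse 2). In Gne+/- C3-/- against C3-/- they ranged from 0 to 5 (0 without C3-/- mouse 5, 1 without Gne+/- C3-/- mouse 3, 5 without wildtype mouse 1, Gne+/- mouse 8 or Gne+/- C3-/- mouse 5). In the difference they ranged from 1 to 3 (1 without wildtype mouse 2, 5, 6 or 8, Gne+/- mouse 1, 3, 4 or 5, C3-/- mouse 1 or 8, or Gne+/- C3-/- mouse 4, 5 or 8). In Gne+/- C3-/- against Gne+/- they ranged from 0 to 4 (0 without wildtype mouse 2, 6 or 7, Gne+/- mouse 3 or 5, or Gne+/- C3-/- mouse 4, 5 or 8, and 1 without Gne+/- mouse 2, 4 or 7, or Gne+/- C3-/- mouse 3). What depth, from 13.5 M counts, limits was not tested apart from the spread between mice.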

Other observations

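Lists for neighbouring tissues and retinal neurons stood near the threshold without passing. In Gne+/- C3-/- against Gne+/- mice, retinal ganglion cell genes had 8 of 12 members positive (median 0.26, camera adjusted p = 0.0684; adjusted p = 0.371 with an estimated correlation), with Pou4f1, a ganglion cell transcription factor, at 0.51 (SE 0.158) and the neurofilament gene Nefh at 0.50 (SE 0.189). Of this list 0 genes passed over all genes and 1 adjusted over the list alone. Pigment epithelium and melanocyte genes did not pass in Gne+/- C3-/- against C3-/- (8 of 11 positive, median 0.46, adjusted p = 0.0659; adjusted p = 0.511 with an estimated correlation), with Rgr at 0.62 (SE 0.283) and Ttr at 0.53 (SE 0.3).

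The cone and OFF bipolar cell list, which did not pass in Gne+/- against wildtype, was called in 2 of 12 alternative settings and without 1 of 27 libraries, and its adjusted p ranged from 0.0318 to 0.751 over these. The lens list was called there in 8 of 12 settings and the sialic acid synthesis list, Gne included, in 11 of 12 (adjusted p from 4.4e-12 to 0.897 and from 6.35e-05 to 0.347). In Gne+/- C3-/- against C3-/-, the immediate early genes were called in 9 of 12 settings, and the activated microglia and lysosome list in 6 of 12 settings and without 22 of 27 libraries (from 5.24e-06 to 0.812 and from 0.00673 to 0.725).

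The leading component of the residuals, chosen for study after seeing the data, held 38.3% of the residual variance over 9425 genes, with wildtype mouse 6 (0.48) and Gne+/- mouse 5 (0.46) at one end and wildtype mouse 2 (-0.41) at the other. Gne was lower by 1.48 log2 units in run 2 than in run 1 (log2 fold change -1.48). The sum of Rps13, Rps13-ps1 and Rps13-ps2 was 273 ± 66, 254 ± 85.2, 265 ± 75 and 304 ± 95.2 CPM in wildtype, Gne+/-, C3-/- and Gne+/- C3-/- mice.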
